A study of Homo sapiens with 48 samples.

How the data were processed

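The series holds 48 samples from 3 established human pancreatic ductal adenocarcinoma (PDAC) cell lines. RNA-seq covered 30 libraries in 10 groups of 3. ASPC1 and CFPAC1 each gave 4 groups: transfection with a control siRNA (siCTRL), transfection with an siRNA against ZNF274 (siZNF274), treatment with the solvent DMSO, and treatment with 5 µM azacitidine (AZA), an inhibitor of DNA methyltransferases. Panc3.27 gave 2 groups: an empty vector and a vector overexpressing ZNF274 (OE). Per the labels, 500 ng of total RNA entered a ribosomal-RNA-depleted, stranded library preparation. The other 18 samples are CUT&RUN profiles (antibody-guided cleavage of chromatin) of ASPC1 carrying a control (shCTRL) or a ZNF274 hairpin (shZNF274) induced with 1 µg/ml doxycycline for 9 days. They were profiled for ZNF274, for the repressive histone mark H3K9me3 and with a control IgG. From CUT&RUN, the H3K9me3 broad peak list of the whole series was used here, and coverage per sample was not analysed here.

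For RNA-seq, the authors deposited whole-number counts per gene, without normalization. The submitters' processing notes name STAR 2.7.10b, FastQC and the build hg38. The counting program, its strand setting and the annotation release are not given in the sources used here, so values of genes that overlap others or have close paralogs carry that uncertainty. The table lists 36843 genes, of which 19955 are protein-coding and 16888 are long non-coding, and 5032 had no count in any library. Positions and gene types are those written in the deposited count table, and 36717 of its gene identifiers were matched to a table of symbols after dropping the version suffix. Totals ran from 31415743 to 43383141 counts per library. Among the 30 within-group pairs of libraries none were identical, and the chi-square per gene between libraries of a group ran from 2.83 to 27.7.

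For CUT&RUN, the deposited peak list gives a position, the group or groups in which the authors called the peak, an annotation class, the authors' call for shZNF274 against shCTRL (Down, Up, not changed or not tested) and a score. The deposited score has the same value in all peaks, so it ranks nothing. The notes name DRAGEN, Trim Galore, Bowtie2, MACS2, SAMtools, bedtools, HOMER, Subread, featureCounts and edgeR with the builds GRCh38 and hg38. Their versions, and whether peaks were called per sample or on pooled samples, are not given in the sources used here.

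Each line was fitted by itself with edgeR 4.0.16 in R 4.3.3, with 12 libraries for ASPC1, 12 for CFPAC1 and 6 for Panc3.27. Genes passed edgeR's filterByExpr on the group, libraries were scaled by TMM factors, and each contrast was tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05 over the tested genes. Levels are TMM-scaled counts per 1e6 counts (CPM) within a line, as mean ± SD over 3 libraries, unless named as CPM of the total count. Fold changes are those of the fit. The design text calls the replicates biological triplicates, but the labels do not say whether these were separate cultures, so the p-values measure the spread between these samples. Intervals and floors of counts cover counting error only.

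The difference between lines was tested as an interaction in 1 edgeR fit over 24 libraries. Gene lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, provided that at least 3 members were tested. A repeat with an estimated correlation and fry, a self-contained test of whether a list's genes move on balance 1 way, were run beside it. The 28 lists hold 775 matched genes, and 6 entries found no match. They are the H3K9me3 machinery, clustered protocadherins, Prader-Willi locus, classical PDAC, basal-like PDAC, epithelial, mesenchymal, foregut and ductal factors, acinar, neuroendocrine and neural, squamous, interferon response, antigen presentation, cancer-testis and germline, DNA methylation machinery, azacitidine uptake and metabolism, cell cycle, p53 and damage targets, integrated stress response, transcription kinases, drug efflux, NF-kB and inflammatory, cholesterol synthesis, replication-dependent histones, mitochondrial mRNA, leukocyte, fibroblast and endothelial lists.

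Further sets were genes with at least 50% of the gene body under the H3K9me3 peaks of ASPC1, used for every line. The others were genes whose symbol starts with ZNF and a digit, over all chromosomes and for chromosome 19 alone. ZNF274 was left out of these sets of zinc finger genes, and it is included where genes or peaks are counted by cover or overlap. The genes called in 1 comparison were also tested with camera as sets in another, with adjustment over 12 such tests. The 3 sets of peaks and zinc finger genes were also tested for a difference between lines, adjusted over 6 tests. They gave 15 planned tests over 5 comparisons, adjusted together, and 35 tests of sets added later, adjusted together. Cover of gene classes and classes of peaks were compared with Fisher's exact test in SciPy 1.17.1, two-sided, with Benjamini-Hochberg adjustment over 22 tests for the peak classes. Tables were handled with pandas 2.3.3 and NumPy 2.4.6 in Python 3.11.15, and plots were drawn with Matplotlib 3.10.9.

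Named genes followed a rule. In each comparison they are ZNF274, the 8 genes with the highest and the 8 with the lowest log2 fold change among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the libraries of both groups, and up to 4 members of each list with the smallest p. Clone-based names and chromosome Y were left out, and a few genes that the rule names are not reported here. A fold against a control group without counts is given as a bound from a floor of 3 counts over the control group, and 1 to 3 control counts give a ratio with its 95% counting interval. Differences between lines of genes that are members of a list are covered by the difference of the list. The lists, the rule for named genes, the main tests and 90 alternatives were chosen before the data were examined, and 10 alternatives were added afterwards.

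The alternatives were median-of-ratios and upper quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, the replicate number as a block, a fit of the 6 compared libraries, each library left out in turn, other tests of the lists and other limits of peak cover. The tests were also tested on simulated data, in which 200 genes were changed. These were drawn from negative binomial distributions with each gene's mean over the line and the spread fitted as a trend on expression. At a 2-fold change, between 80.8% and 87.9% of the changed genes were recovered within a line, and 60.2% and 59.8% for the differences between lines. At a 1.5-fold change the share within a line lay between 66.0% and 73.0%, and for the differences between lines it was 37.8% (siZNF274) and 44.4% (azacitidine). Genes called without a change made up between 1.03% and 7.27% of the calls. A simulated rise of the cholesterol list by 1.5-fold was called in all 5 comparisons, and no other list was called there. Simulated genes were drawn independently, so this does not test false calls of lists whose genes move together. Far fewer genes were changed there than edgeR called in any real comparison, so the shares recovered and falsely called may differ in the real data.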

Results

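The data are gene counts of 30 RNA-seq libraries, 3 per group, from the PDAC lines ASPC1, CFPAC1 and Panc3.27, with totals between 31415743 and 43383141 counts, and 1 list of H3K9me3 broad peaks from ASPC1. ZNF274 is a KRAB zinc finger protein known to bind the 3-prime ends of zinc finger genes and to recruit the machinery that places H3K9me3, a mark of silent chromatin. The series concerns ZNF274 in lineage plasticity and in resistance to inhibitors of the kinase CDK7. Its design pairs siRNA against ZNF274 and azacitidine in ASPC1 and CFPAC1 with overexpression of ZNF274 in Panc3.27. The siRNA and the azacitidine comparisons used separate control groups.

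ZNF274 itself (ENSG00000171606.18, build hg38, chromosome 19, 58183029 to 58213562) was not lower in the libraries labelled siZNF274 than in their controls. In ASPC1 its level was 19.4 ± 2.93 CPM (SD, n = 3) with siZNF274 and 17.6 ± 2.61 CPM with siCTRL, a fold of 1.11 with a 95% interval from 0.939 to 1.31. In CFPAC1 it was 32.8 ± 1.47 CPM and 34.4 ± 1.12 CPM, a fold of 0.955 with an interval from 0.880 to 1.04. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.305 for ASPC1 (log2 fold change 0.15, SE 0.11) and 0.423 for CFPAC1 (log2 fold change -0.07, SE 0.056). In ASPC1 it was 0.28 without siCTRL replicate 3 (edgeR, adjusted p = 0.0445), a difference upwards. Azacitidine raised ZNF274 by 1.40-fold in ASPC1, from 13.7 ± 1.18 to 19.2 ± 0.80 CPM (edgeR, adjusted p = 0.00317, higher in 3 of 3 libraries). In CFPAC1 the azacitidine fold was 1.12, from 28.5 ± 0.45 to 31.8 ± 0.95 CPM (edgeR, adjusted p = 0.0464), and this call ended without any 1 of 5 of the 6 libraries, with adjusted p up to 0.148 without AZA replicate 3. In Panc3.27 the overexpression raised ZNF274 by 2.76-fold, from 49.1 ± 1.54 to 136 ± 2.90 CPM, with an interval from 2.58 to 2.96 (edgeR, adjusted p = 4.17e-11). The vector libraries of Panc3.27, which the design text describes as a line with low ZNF274, had more ZNF274 in CPM of the total count (49.1 ± 2.13) than the siCTRL libraries of ASPC1 (17.1 ± 2.37) and CFPAC1 (34.0 ± 1.40). These values are mRNA from lines handled differently. Whether the design text means mRNA or protein is not given in the sources used here, so the values do not contradict it.

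**Figure D1:**
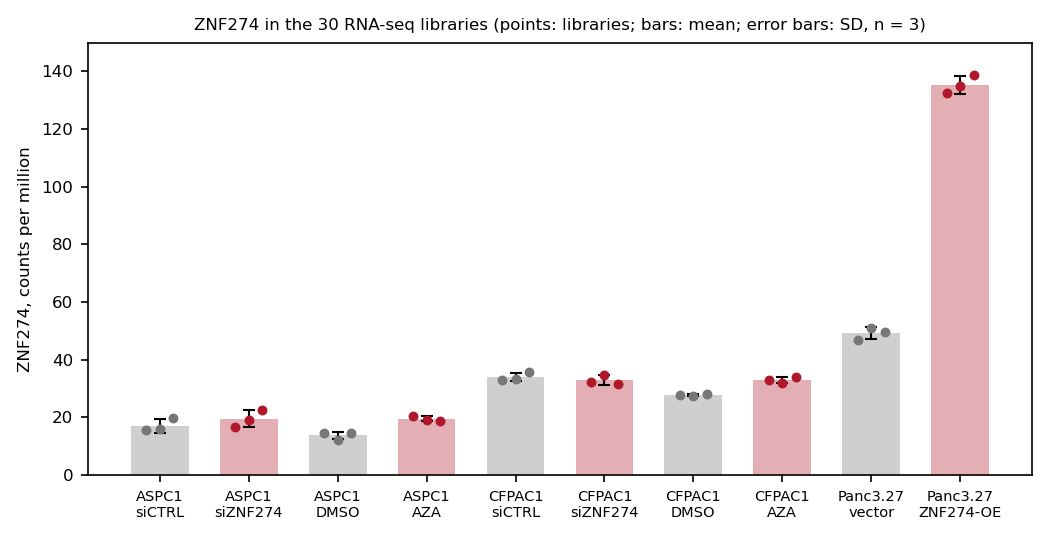
ZNF274 in CPM of the total count in each of the 30 libraries (points) with the mean and SD of the 3 libraries of each group. Means were 19.5 with siZNF274 and 17.1 with siCTRL in ASPC1, 32.9 and 34.0 in CFPAC1, and 135 with overexpression and 49.1 with the vector in Panc3.27.

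The libraries labelled siZNF274 were compared with siCTRL in ASPC1 to ask which genes change when ZNF274 is targeted. CDH1, the adherens junction protein E-cadherin, fell from 123 ± 7.47 to 42.8 ± 3.19 CPM (n = 3 each). The gene with the strongest rise among those named by size was BMF (ENSG00000104081.14, chromosome 15, 40087890 to 40108892), a BH3-only promoter of apoptosis, which went from 1.28 ± 0.033 to 10.3 ± 0.77 CPM, 8.03-fold. CDKN1C, a cyclin-dependent kinase inhibitor, rose 7.23-fold, FNDC4 6.92-fold, COL7A1, the anchoring-fibril collagen, 6.77-fold (5.42 ± 0.58 to 36.6 ± 2.48 CPM), CDSN 6.51-fold, the macrophage growth factor CSF1 6.16-fold (5.32 ± 0.60 to 32.7 ± 2.20 CPM), LIMD2 6.08-fold and ADAMTS7 5.09-fold. The strongest fall was that of KRT23 (ENSG00000108244.17, chromosome 17, 40922700 to 40937646), a type I keratin, from 19.8 ± 3.42 to 1.71 ± 0.18 CPM, 11.6-fold. SLC44A4 was 8.74-fold lower, the intestinal glucose transporter gene SLC5A1 5.85-fold, PLEKHB1 5.25-fold, the tumour antigen CEACAM5 5.14-fold (83.8 ± 4.29 to 16.3 ± 1.43 CPM), SLC28A3 4.94-fold, the stress cytokine GDF15 4.55-fold (37.3 ± 10.8 to 8.15 ± 1.02 CPM) and the gap junction gene GJB1 4.47-fold. For each of the genes named by size the 3 libraries of 1 group all lay above the 3 of the other, as the naming rule required.

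By list, 1 of 24 tested epithelial genes rose and 19 fell in ASPC1, or 1 and 20 adjusted over the list alone, with a median log2 fold change of -0.55 (camera, adjusted p = 5.56e-14, and adjusted p = 0.0518 with an estimated correlation). EPCAM fell from 870 ± 29.3 to 498 ± 14.4 CPM, the splicing regulator ESRP1 from 33.1 ± 1.40 to 12.8 ± 1.09 and the tight junction gene CLDN1 from 53.1 ± 1.56 to 21.8 ± 1.39. Of 22 mesenchymal genes 14 rose and 2 fell, or 16 and 2 adjusted over the list alone, with a median of 0.68 (camera, adjusted p = 5.69e-07, and adjusted p = 0.0711 with an estimated correlation). The myelin and membrane protein gene PMP22 rose from 27.1 ± 0.27 to 63.6 ± 3.78 CPM and the repressor of E-cadherin ZEB1 from 41.6 ± 3.06 to 81.1 ± 1.56, while TGFBI fell from 404 ± 4.71 to 307 ± 9.09. Of 12 squamous genes none rose and 9 fell, also adjusted over the list alone, with a median of -0.83 (camera, adjusted p = 1.90e-05), and this list alone among those of ASPC1 siZNF274 kept its call with an estimated correlation (adjusted p = 0.0461 with an estimated correlation). Its members KLK7, a kallikrein protease of shed skin layers, went from 32.9 ± 1.16 to 12.9 ± 0.63 CPM and the desmosome gene DSG3 from 90.5 ± 4.07 to 45.3 ± 0.96. Of 19 genes of the classical PDAC subtype 4 rose and 8 fell, also adjusted over the list alone, with a median of -0.16 (camera, adjusted p = 0.00195, and adjusted p = 0.198 with an estimated correlation). Among them AGR2 fell from 161 ± 10.7 to 73.1 ± 4.82 CPM and LGALS4 from 367 ± 26.1 to 198 ± 7.0.

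Cholesterol synthesis rose in ASPC1, with 22 of 25 genes higher and none lower, also adjusted over the list alone, and a median of 0.46 (camera, adjusted p = 6.71e-11, and adjusted p = 0.209 with an estimated correlation). HMGCS1 went from 153 ± 11.7 to 295 ± 3.95 CPM. Cell cycle genes fell, with 2 of 51 higher and 40 lower, or 2 and 41 adjusted over the list alone, and a median of -0.37 (camera, adjusted p = 2.01e-10, and adjusted p = 0.319 with an estimated correlation). The mitotic kinase PLK1 went from 183 ± 15.4 to 105 ± 6.16 CPM and UBE2C from 139 ± 3.42 to 88.3 ± 2.97. Replication-dependent histones, a multigene family whose members share sequence, had none of 39 higher and 24 lower, or none and 26 adjusted over the list alone, with a median of -0.35 (camera, adjusted p = 3.06e-05, and adjusted p = 0.526 with an estimated correlation). Among them H2BC7 went from 99.6 ± 9.01 to 53.9 ± 3.80 CPM. The integrated stress response, the ATF4-driven program of amino acid supply, had 2 of 27 genes higher and 22 lower, or 2 and 23 adjusted over the list alone, with a median of -0.62 (camera, adjusted p = 1.44e-07, and adjusted p = 0.357 with an estimated correlation). In it the amino acid transporter gene SLC7A5 fell 4.23-fold, from 953 ± 110 to 225 ± 16.3 CPM. The siCTRL libraries of ASPC1 that these values are set against had this list raised against DMSO, with a median of 1.41 and 25 of 27 genes higher.

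NF-kB and inflammatory genes rose in ASPC1, with 13 of 22 higher and 5 lower, also adjusted over the list alone, and a median of 0.44 (camera, adjusted p = 0.00125, and adjusted p = 0.209 with an estimated correlation). The adhesion molecule ICAM1 went from 1.56 ± 0.28 to 6.64 ± 0.73 CPM and NFKB2 from 59.9 ± 6.74 to 110 ± 3.93, while LCN2 fell from 192 ± 20.9 to 62.8 ± 5.78. The siCTRL libraries of ASPC1 already had this list raised against DMSO, with a median of 0.51, 14 of 22 genes higher and 4 lower. Genes of azacitidine uptake and metabolism had 1 of 16 higher and 9 lower, or 2 and 9 adjusted over the list alone, with a median of -0.21 (camera, adjusted p = 0.0156, and adjusted p = 0.122 with an estimated correlation). They include the nucleoside transporter gene SLC28A3, from 7.71 ± 0.57 to 1.54 ± 0.49 CPM, and the nucleotide phosphohydrolase gene SAMHD1, from 8.65 ± 0.84 to 4.36 ± 0.37. Over all 16186 tested genes, edgeR called 3483 higher and 3917 lower, of which 611 and 423 changed at least 2-fold. With upper quartile scaling it called 4221 higher and 3195 lower, so which direction had more genes depended on the scaling. The nuclear transcript MALAT1 took 1.16 ± 0.12% of the counts with siZNF274 and 0.81 ± 0.21% with siCTRL.

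In CFPAC1, the libraries labelled siZNF274 had a lower squamous and a higher mesenchymal list than siCTRL. KDR, the receptor of VEGF, rose from 2.62 ± 0.61 to 15.3 ± 3.59 CPM (n = 3 each), 5.81-fold, and the fibronectin gene FN1 rose from 37.7 ± 2.50 to 90 ± 2.59 CPM. The strongest rise among genes named by size was that of ANXA13 (ENSG00000104537.17, chromosome 8, 123680794 to 123737402), an epithelial annexin, from 1.5 ± 0.59 to 9.11 ± 2.92 CPM, 6.07-fold. The cystatin genes CST4 and CST1, close paralogs, were 4.79-fold and 3.79-fold higher, the TGF-beta co-receptor ENG 3.42-fold, RRAD 3.05-fold and MEDAG 3.02-fold. KRT6A, a keratin with close paralogs, was 4.61-fold lower, and IL1RL1 (ENSG00000115602.17, chromosome 2, 102311502 to 102352037), the receptor of interleukin 33, fell from 11.1 ± 0.26 to 2.46 ± 0.24 CPM, 4.51-fold. NMUR2 was 3.37-fold lower, TNFSF18 2.71-fold, the proton pump subunit ATP6V0E1 2.62-fold (72.7 ± 10.7 to 27.7 ± 0.56 CPM), ZBED2 2.60-fold, GPR141 2.53-fold and CAPN8 2.47-fold.

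By list, 1 of 51 cell cycle genes rose and 40 fell in CFPAC1, or 1 and 42 adjusted over the list alone, with a median of -0.26 (camera, adjusted p = 1.93e-13, and adjusted p = 0.246 with an estimated correlation). The replication helicase gene MCM4 went from 238 ± 30.5 to 151 ± 6.03 CPM and BRCA1 from 108 ± 6.25 to 84.2 ± 3.20. None of 26 epithelial genes rose and 19 fell, also adjusted over the list alone, with a median of -0.32 (camera, adjusted p = 1.26e-09, and adjusted p = 0.136 with an estimated correlation). CDH1 went from 429 ± 6.94 to 277 ± 29.0 CPM and CLDN1 from 39.1 ± 9.30 to 18.8 ± 1.14. Of 28 mesenchymal genes 12 rose and 1 fell, or 16 and 2 adjusted over the list alone, with a median of 0.21 (camera, adjusted p = 2.94e-06). ZEB1 rose from 33.1 ± 4.06 to 57.4 ± 6.76 CPM. The siCTRL libraries of CFPAC1 that these values are set against had the mesenchymal list lowered against DMSO, with a median of -0.21, 3 of 28 genes higher and 10 lower. Of 22 basal-like genes 2 rose and 10 fell, also adjusted over the list alone, with a median of -0.15 (camera, adjusted p = 1.71e-07), among them TNS4, from 438 ± 20.5 to 182 ± 20.3 CPM, and FGFBP1, a carrier of fibroblast growth factors, from 134 ± 13.4 to 58.6 ± 3.14. None of 15 squamous genes rose and 8 fell, also adjusted over the list alone, with a median of -0.55 (camera, adjusted p = 1.32e-05). Among them TRIM29 went from 6.81 ± 0.60 to 2.83 ± 0.21 CPM. Of 5 endothelial markers 3 rose and none fell, also adjusted over the list alone, with a median of 0.55 (camera, adjusted p = 2.18e-04), and these were KDR, ESAM (15.1 ± 1.81 to 22 ± 2.22 CPM) and TIE1 (0.195 ± 0.13 to 0.710 ± 0.14 CPM). The basal-like, squamous, mesenchymal and endothelial calls of CFPAC1 siZNF274 held with an estimated correlation.

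Antigen presentation genes rose in CFPAC1, with 8 of 24 higher and none lower, or 9 and none adjusted over the list alone, and a median of 0.10 (camera, adjusted p = 0.0302, and adjusted p = 0.297 with an estimated correlation). The peptide transporter gene TAP1 went from 138 ± 7.63 to 168 ± 2.38 CPM. The call ended without siZNF274 replicate 1 (camera, adjusted p = 0.148) or siCTRL replicate 3 (0.0762). Drug efflux genes had 4 of 11 higher and none lower, or 5 and 1 adjusted over the list alone, with a median of 0.20 (camera, adjusted p = 0.0463, and adjusted p = 0.148 with an estimated correlation). Among them the efflux pump gene ABCG2 went from 3.39 ± 0.74 to 5.92 ± 0.90 CPM. That call ended without siCTRL replicate 2 (camera, adjusted p = 0.0562), siCTRL replicate 3 (0.0793) or siZNF274 replicate 3 (0.0698). Over all 18103 tested genes, edgeR called 2099 higher and 2384 lower, of which 216 and 91 changed at least 2-fold. With upper quartile scaling it called 2429 higher and 2041 lower, so here too the balance depended on the scaling. MALAT1 took 0.57 ± 0.09% of the counts with siZNF274 and 0.50 ± 0.06% with siCTRL.

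**Figure D2:**
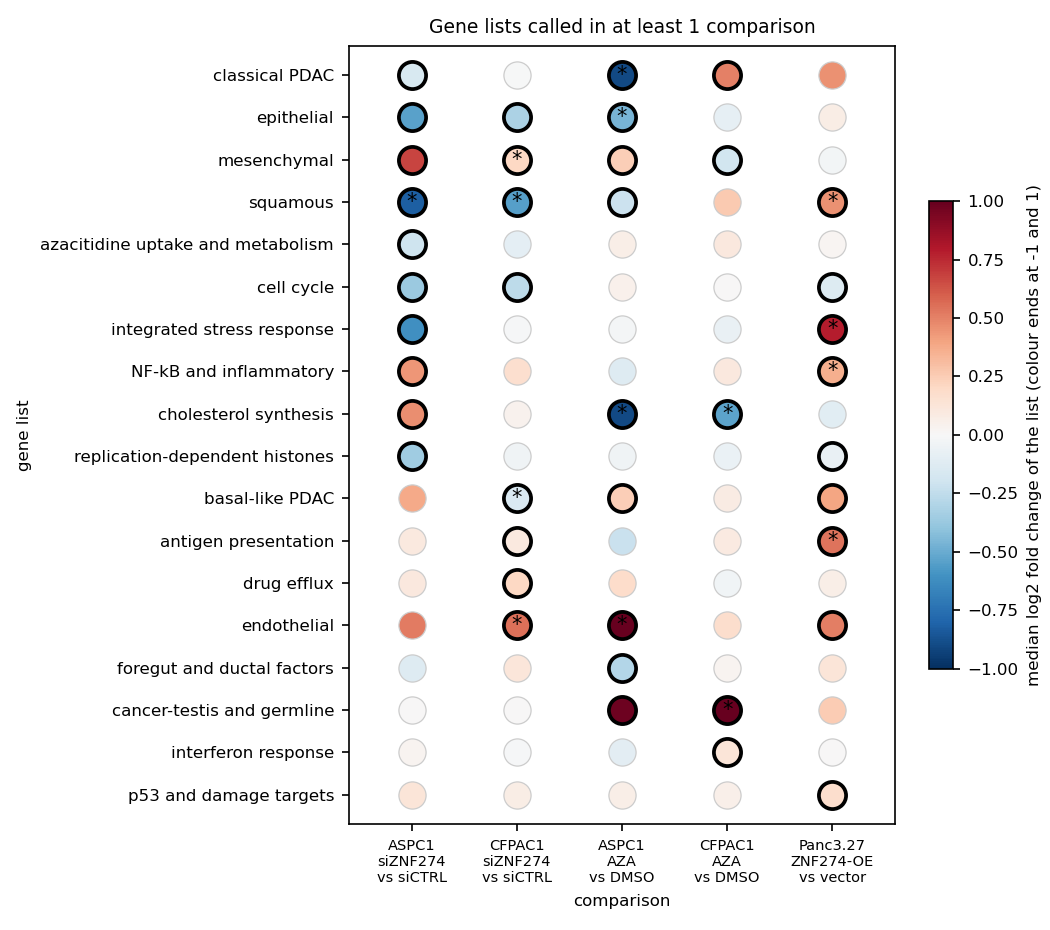
Median log2 fold change (colour) of each gene list in the 5 comparisons, with a bold outline where camera called the list and a star where the call held with an estimated correlation. The integrated stress response had a median of 0.78 in Panc3.27 with ZNF274 overexpression and -0.62 in ASPC1 with siZNF274. In CFPAC1 with siZNF274 the median of this list lay between -0.010 and 0.013 over the scalings. Cholesterol synthesis had medians of -0.90 and -0.53 with azacitidine in ASPC1 and CFPAC1.

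The siZNF274 changes of both lines were set side by side to ask which genes moved alike. Of 15284 genes tested in both lines, 1037 were higher in both where 393 were expected from the counts alone, and 1453 were lower in both where 548 were expected, while 86 and 159 went opposite ways. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.39 and Spearman's rho was 0.44. The genes called higher in ASPC1 ranked higher in CFPAC1 as a set (camera, adjusted p = 5.62e-18) and those called lower ranked lower (camera, adjusted p = 6.81e-20). The laminin gene LAMA4 was 2.47-fold higher in ASPC1 (64.7 ± 1.66 to 160 ± 2.74 CPM) and 2.57-fold higher in CFPAC1 (17.7 ± 1.55 to 45.5 ± 1.91 CPM). The matrix gene THBS2 went from 425 ± 10.7 to 868 ± 14.3 CPM in ASPC1 and was 1.60-fold higher in CFPAC1. ATP6V0E1 was 3.50-fold lower in ASPC1 (75.1 ± 7.87 to 21.5 ± 1.89 CPM) and 2.62-fold lower in CFPAC1, the kinase gene STK24 was 3.36-fold and 1.96-fold lower, and MDM2, the ubiquitin ligase of p53, was 2.04-fold and 1.72-fold lower. The p53 and damage list passed the test in neither line.

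Azacitidine in ASPC1 was compared with DMSO to ask which genes respond to this inhibitor of DNA methyltransferases. The classical PDAC and cholesterol synthesis lists fell. GPA33, an intestinal surface antigen, fell from 288 ± 10.3 to 52.2 ± 5.22 CPM (n = 3 each), 5.52-fold, and MMP1, the interstitial collagenase, rose from 0.789 ± 0.14 to 19.2 ± 1.67 CPM, 24.2-fold. The strongest rise among genes named by size was NPTX1 (ENSG00000171246.6, chromosome 17, 80466834 to 80477843), a neuronal pentraxin, 27.8-fold, from 0.274 ± 0.13 to 7.75 ± 1.27 CPM. TOX2 was 21-fold higher, the ERK phosphatase gene DUSP5 12.8-fold, the growth factor gene BMP6 11.9-fold, PLIN4 10.8-fold, SLC37A2 9.38-fold and FERMT3, an integrin activator of blood cells, 8.58-fold. SLC5A1 (ENSG00000100170.10, chromosome 22, 32043261 to 32113029) was 6.84-fold lower, from 3.56 ± 0.21 to 0.518 ± 0.14 CPM, PRR15L 5.69-fold, COL28A1 5.56-fold, the intestinal lectin gene REG4 5.09-fold, GJB1 4.88-fold, SLC44A4 4.59-fold and ARHGEF38 4.57-fold.

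By list, none of 25 cholesterol synthesis genes rose and 24 fell with azacitidine in ASPC1, also adjusted over the list alone, with a median of -0.90 (camera, adjusted p = 4.49e-41). SREBF2, a transcriptional regulator of the pathway, went from 307 ± 2.08 to 165 ± 3.19 CPM. None of 24 epithelial genes rose and 20 fell, also adjusted over the list alone, with a median of -0.47 (camera, adjusted p = 4.30e-15). Among them EPCAM went from 830 ± 13.5 to 482 ± 2.43 CPM and CDH1 from 118 ± 7.44 to 49.6 ± 3.13. Of 19 classical PDAC genes 2 rose and 12 fell, also adjusted over the list alone, with a median of -0.90 (camera, adjusted p = 1.55e-14). Among them TSPAN8 went from 626 ± 19.7 to 231 ± 26.2 CPM and the lysozyme gene LYZ from 273 ± 8.11 to 101 ± 12.9. All 4 tested endothelial markers rose, also adjusted over the list alone, with a median of 1.91 (camera, adjusted p = 1.97e-04), from low levels: CLDN5 from 0.0357 ± 0.015 to 2.63 ± 0.28 CPM, ESAM from 0.713 ± 0.12 to 1.84 ± 0.28, TIE1 from 0.0981 ± 0.031 to 0.553 ± 0.18 and VWF from 0.396 ± 0.13 to 0.819 ± 0.21. The filter asked for counts in any group, so CLDN5 and TIE1 were tested through a group other than DMSO. Markers silent in every group were left out. The share of endothelial markers that rose, their median and their list test are therefore in part set by the filter. The cholesterol, epithelial, classical and endothelial calls held with an estimated correlation.

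Of 22 mesenchymal genes 10 rose and 3 fell with azacitidine in ASPC1, or 11 and 3 adjusted over the list alone, with a median of 0.24 (camera, adjusted p = 1.18e-05, and adjusted p = 0.0662 with an estimated correlation). Among them the fibronectin receptor gene ITGA5 went from 4.98 ± 0.34 to 28.9 ± 1.57 CPM. Foregut and ductal factors had 2 of 19 higher and 10 lower, also adjusted over the list alone, with a median of -0.29 (camera, adjusted p = 1.97e-04, and adjusted p = 0.0937 with an estimated correlation). The nuclear receptor HNF4G went from 97.0 ± 2.28 to 34.2 ± 2.42 CPM and HNF4A from 268 ± 10.0 to 168 ± 3.52. Of 14 basal-like genes 4 rose and 2 fell, also adjusted over the list alone, with a median of 0.24 (camera, adjusted p = 8.98e-04, and adjusted p = 0.0509 with an estimated correlation). Among them KRT7 went from 2.67 ± 0.26 to 14.2 ± 0.62 CPM and FAM83A from 332 ± 17.5 to 707 ± 2.78. Of 12 squamous genes 1 rose and 6 fell, also adjusted over the list alone, with a median of -0.22 and a mean of 0.07 that differed in sign, and the test pointed down (camera, adjusted p = 0.0184, and adjusted p = 0.0936 with an estimated correlation). KLK7 fell from 25.5 ± 0.51 to 10.5 ± 0.27 CPM, and KRT13 rose to 1.39 ± 0.16 CPM from 0.0786 ± 0.050.

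Of 8 cancer-testis and germline genes, a class silenced by DNA methylation in most adult tissues, 3 rose and 1 fell in ASPC1 with azacitidine, or 4 and 1 adjusted over the list alone, with a median of 0.98 (camera, adjusted p = 0.0257, and adjusted p = 0.0936 with an estimated correlation). MAGEA4 was at least 38.0-fold higher and TKTL1 at least 20.7-fold higher than DMSO libraries without a count, and MAEL had 78 counts against 1, a ratio of 78.0 with a counting interval from 13.6 to 3121. MAGEA4, TKTL1 and MAEL passed the filter only through counts in a group other than DMSO, and members silent in every group were left out. The share that rose, the median and the list test are therefore in part set by the filter. The list's adjusted p was 0.0579 (camera) with the replicate number as a block. Over all 16186 tested genes, edgeR called 2792 higher and 3004 lower, of which 559 and 296 changed at least 2-fold. MALAT1 took 1.36 ± 0.06% of the counts with azacitidine and 0.83 ± 0.08% with DMSO.

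Azacitidine in CFPAC1 raised germline genes and lowered cholesterol synthesis. UPK1B (ENSG00000114638.8, chromosome 3, 119173517 to 119205143), a plaque protein of urothelium, rose from 2.13 ± 0.20 to 40.4 ± 3.95 CPM (n = 3 each), 18.9-fold. INPP5D, an inositol phosphatase of blood cells, was 15.8-fold higher (0.438 ± 0.057 to 6.96 ± 0.43 CPM), the germ cell gene GCNA 9.61-fold, the calcium-binding gene S100P 7.19-fold (3.95 ± 0.56 to 28.4 ± 2.63 CPM), KLHDC7B 5.95-fold, PECAM1 5.46-fold, KRT13 4.39-fold and the mucin gene MUC5B 4.20-fold. ABI3BP (ENSG00000154175.18, chromosome 3, 100749156 to 100993515), a matrix protein, fell from 65.8 ± 8.88 to 13.7 ± 0.29 CPM, 4.79-fold. TNFSF18 was 4.61-fold lower, the cytokine IL11 3.30-fold, CXCL14 3.20-fold, FAT3 3.10-fold, LINGO2 2.96-fold, the collagen gene COL8A1 2.91-fold (25.6 ± 1.33 to 8.78 ± 0.081 CPM) and CPED1 2.89-fold.

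Of 22 cancer-testis and germline genes 17 rose and none fell in CFPAC1, or 18 and none adjusted over the list alone (camera, adjusted p = 7.48e-21). The median log2 fold change was 3.74, and 3.73 with the 3 members without a control count set at their bound. Another 6 members had 1 to 3 counts over the DMSO libraries. The filter asked for counts in any group, so these members were tested only because another group held counts. Members silent in every group were left out. The share that rose, the median and the list test are therefore in part set by the filter. SPANXB1, of a family of close paralogs, had 434 counts against 2, a ratio of 194 with a counting interval from 53.4 to 1607. MAGEB2 had a ratio of 35.2, the piRNA pathway gene MAEL had a ratio of 18.9, and TDRD1 was at least 33.4-fold and the RNA-binding gene DAZL at least 31.6-fold higher than control libraries without a count. Cholesterol synthesis had none of 25 higher and 21 lower, or 1 and 23 adjusted over the list alone, with a median of -0.53 (camera, adjusted p = 3.80e-28). Among them DHCR7 went from 241 ± 4.65 to 150 ± 6.72 CPM and SQLE from 162 ± 6.31 to 97.9 ± 4.02. Both calls held with an estimated correlation.

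Of 16 classical PDAC genes 8 rose and 1 fell with azacitidine in CFPAC1, or 10 and 1 adjusted over the list alone, with a median of 0.50 (camera, adjusted p = 2.36e-04, and adjusted p = 0.130 with an estimated correlation). Among them the trefoil peptide genes TFF1 went from 1.89 ± 0.29 to 7.81 ± 0.47 CPM and TFF2 from 22.8 ± 4.44 to 40.3 ± 2.48. Of 28 mesenchymal genes 3 rose and 13 fell, or 5 and 13 adjusted over the list alone, with a median of -0.19 (camera, adjusted p = 3.95e-04, and adjusted p = 0.102 with an estimated correlation). Among them the receptor kinase gene AXL went from 1519 ± 81.1 to 812 ± 7.30 CPM and the collagen crosslinker LOXL2 from 63.4 ± 1.66 to 34.1 ± 0.84. Interferon response genes had 10 of 48 higher and none lower, or 8 and none adjusted over the list alone, with a median of 0.13 (camera, adjusted p = 0.0411, and adjusted p = 0.781 with an estimated correlation). Among them STING1 went from 44.7 ± 3.39 to 55.6 ± 1.60 CPM. That call ended without AZA replicate 2 (camera, adjusted p = 0.182) or DMSO replicate 3 (0.0651). Over all 18103 tested genes, edgeR called 2207 higher and 2445 lower, of which 379 and 130 changed at least 2-fold, and with upper quartile scaling it called 2940 higher and 1914 lower. MALAT1 took 0.55 ± 0.06% of the counts with azacitidine and 0.42 ± 0.07% with DMSO.

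Azacitidine moved 771 genes up and 870 down in both lines, where 322 and 414 were expected, out of 15284, and 292 and 229 went opposite ways, where 383 and 349 were expected, with Pearson's r of 0.29 and Spearman's rho of 0.28 across genes. The sets called in ASPC1 ranked the same way in CFPAC1 (camera, adjusted p = 2.43e-06 for higher and adjusted p = 1.03e-07 for lower). The call of the higher set did not hold (adjusted p = 0.0581 with an estimated correlation). Within ASPC1, siZNF274 and azacitidine shared 1125 genes higher and 1399 lower, where 601 and 727 were expected out of 16186 (camera, adjusted p = 2.53e-06 for higher and adjusted p = 1.54e-08 for lower), and 435 and 414 went opposite ways, where 646 and 676 were expected. Within CFPAC1 they shared 434 and 569, where 256 and 322 were expected out of 18103, and 333 and 249 went opposite ways, where 283 and 291 were expected. There the genes called lower with siZNF274 ranked lower with azacitidine (camera, adjusted p = 0.00419, and adjusted p = 0.457 with an estimated correlation). Those called higher did not pass the test (camera, adjusted p = 0.244).

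Overexpression of ZNF274 in Panc3.27 was compared with the empty vector to ask which genes change when ZNF274 is raised. Genes of the integrated stress response, of inflammation, of antigen presentation and of the squamous list rose. INHBE, an activin subunit gene induced by ATF4, rose from 18.4 ± 0.97 to 94.4 ± 2.32 CPM (n = 3 each), 5.13-fold. ATP12A (ENSG00000075673.12, chromosome 13, 24680408 to 24712472), a proton pump, rose from 1.43 ± 0.13 to 11.2 ± 0.46 CPM, 7.80-fold, the stress hormone gene FGF21 7.10-fold, MOV10L1 6.97-fold, NUPR1 6.61-fold, the neutrophil antigen gene CD177 6.54-fold, ECM2 5.08-fold and SYNE3 4.48-fold. GALNT16 (ENSG00000100626.17, chromosome 14, 69259277 to 69357033), a glycosyltransferase, fell from 28.5 ± 1.68 to 1.72 ± 0.22 CPM, 16.5-fold. AMOT was 3.38-fold lower, the gluconeogenic enzyme PCK1 2.98-fold, the collagenase MMP13 2.97-fold (510 ± 33.5 to 172 ± 7.98 CPM), AGPAT4 2.84-fold, KCNH2 2.68-fold, ATP2B3 2.45-fold and PPFIA4 2.36-fold.

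Of 31 integrated stress response genes 30 rose and 1 fell in Panc3.27, also adjusted over the list alone, with a median of 0.78 (camera, adjusted p = 2.57e-64). The cystine transporter gene SLC7A11 went from 36.0 ± 1.13 to 95 ± 4.02 CPM, the pseudokinase gene TRIB3 from 87.3 ± 4.16 to 228 ± 4.20 and the serine synthesis enzyme PSAT1 from 190 ± 7.83 to 416 ± 7.17. Of 16 squamous genes 11 rose and 1 fell, or 12 and 1 adjusted over the list alone, with a median of 0.46 (camera, adjusted p = 2.95e-19). Among them KRT14 went from 10.6 ± 0.062 to 38.9 ± 2.43 CPM and the elastase inhibitor PI3 from 47.4 ± 2.28 to 149 ± 7.14. Of 26 NF-kB and inflammatory genes 18 rose and 1 fell, also adjusted over the list alone, with a median of 0.36 (camera, adjusted p = 1.85e-13). Among them LCN2 went from 30.7 ± 0.55 to 91.4 ± 2.13 CPM and SOD2 from 250 ± 12.6 to 546 ± 9.61. Of 25 antigen presentation genes 21 rose and none fell, or 22 and none adjusted over the list alone, with a median of 0.54 (camera, adjusted p = 1.85e-13). Among them the class II gene HLA-DRA went from 6.86 ± 0.23 to 21 ± 1.53 CPM and its chaperone CD74 from 94.5 ± 4.53 to 159 ± 5.73. These 4 calls held with an estimated correlation.

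Of 51 cell cycle genes 4 rose and 32 fell in Panc3.27, or 4 and 34 adjusted over the list alone, with a median of -0.14 (camera, adjusted p = 6.39e-08, and adjusted p = 0.0796 with an estimated correlation). Among them the replication licensing gene CDC6 went from 97.3 ± 2.86 to 64.5 ± 1.07 CPM. Of 28 p53 and damage targets 14 rose and 5 fell, or 14 and 6 adjusted over the list alone, with a median of 0.18 (camera, adjusted p = 8.10e-06, and adjusted p = 0.134 with an estimated correlation). Among them GDF15 went from 26.5 ± 1.77 to 68.1 ± 1.14 CPM and the apoptosis gene BBC3 from 7.32 ± 1.44 to 20.3 ± 2.26. Of 23 basal-like genes 12 rose and 3 fell, also adjusted over the list alone, with a median of 0.39 (camera, adjusted p = 1.97e-04, and adjusted p = 0.0596 with an estimated correlation). Among them KRT17 went from 454 ± 46.5 to 713 ± 14.2 CPM and the EGF receptor ligand AREG from 43.2 ± 1.02 to 77.5 ± 0.69. Of 3 endothelial markers 1 rose and none fell, also adjusted over the list alone, with a median of 0.51 (camera, adjusted p = 0.0283, and adjusted p = 0.241 with an estimated correlation), and this was VWF, from 30.3 ± 0.30 to 55.4 ± 1.91 CPM. Of 39 histone genes 5 rose and 14 fell, or 5 and 15 adjusted over the list alone, with a median of -0.07 (camera, adjusted p = 0.0448, and adjusted p = 0.683 with an estimated correlation). The endothelial and histone calls both ended without vector replicate 3 (camera, adjusted p = 0.0502 and 0.288) or OE replicate 2 (0.0501 for each). Over all 17350 tested genes, edgeR called 3439 higher and 2965 lower, of which 476 and 136 changed at least 2-fold. MALAT1 took 0.40 ± 0.12% of the counts with overexpression and 0.29 ± 0.09% with the vector.

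Genes that moved opposite ways under siZNF274 and overexpression were counted to ask for mirrored responses, although ZNF274 itself was not lower in the libraries labelled siZNF274. Of the 1389 genes lower with siZNF274 in both lines and tested in Panc3.27, 195 were higher with overexpression where 271 were expected from the counts alone, and 535 were lower where 263 were expected. Of the 956 genes higher in both lines, 140 were lower in Panc3.27 where 181 were expected, and 339 were higher where 186 were expected. For single lines, siZNF274 and overexpression shared 809 higher and 982 lower genes in ASPC1 (631 and 691 expected of 14624) and 634 and 832 in CFPAC1 (363 and 419 expected of 15757). Genes higher with siZNF274 and lower with overexpression were 518 in ASPC1 (603 expected) and 242 in CFPAC1 (336 expected), and genes lower with siZNF274 and higher with overexpression were 740 (724 expected) and 346 (452 expected). With an absolute log2 fold change of at least 1, opposite calls were above expectation in both lines, 40 in ASPC1 (7.93 expected) and 9 in CFPAC1 (2.08 expected), beside 34 and 13 shared calls (9.53 and 2.76 expected). The genes called with siZNF274 in ASPC1 did not pass the set test in Panc3.27 (camera, adjusted p = 0.237 for higher and adjusted p = 0.223 for lower). Those of CFPAC1 ranked the same way there (camera, adjusted p = 4.07e-04 for higher and adjusted p = 9.02e-05 for lower), and neither call held (adjusted p = 0.108 and adjusted p = 0.338 with an estimated correlation). Among the genes that did go opposite ways, CEACAM5 had log2 fold changes of -2.36, -1.24 and 1.88 in ASPC1, CFPAC1 and Panc3.27, and CLDN1, ESRP1, TNS4 and the glycolipid transfer gene GLTP were also lower in both lines with siZNF274 and higher with overexpression. NT5E, SERPINB9 and SLC6A6 were higher in both lines with siZNF274 and lower with overexpression.

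The H3K9me3 list of ASPC1 held 63955 broad peaks with a median width of 3633 bp. The authors called 41136 of them in both the shCTRL and the shZNF274 group, 14065 in shZNF274 alone and 8754 in shCTRL alone, and of 63916 tested peaks they called 409 Down and 245 Up with shZNF274. Zinc finger genes lay under this mark far more often than others: 261 of 510 (51.2%, ZNF274 included) had at least 50% of the gene body under peaks, against 1858 of 36280 other genes (5.12%), an odds ratio of 19.4 (Fisher's exact test, p = 9.51e-185). On chromosome 19, where these genes stand in clusters, the share was 182 of 247 (73.7%), and elsewhere it was 79 of 263 (30%). Clustered protocadherins, cell adhesion genes in arrays of chromosome 5, had 10 of 53 covered (18.9%), an odds ratio of 4.31 (Fisher's exact test, p = 3.23e-04). Neighbouring genes can lie under the same broad peak, so the genes are not independent and these p-values are likely too small.

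The peaks the authors called Down were rich in zinc finger genes. Of the 409 Down peaks 72 (17.6%) overlapped a zinc finger gene, against 0.657% of the other tested peaks (odds ratio 32.3, Fisher's exact test, adjusted p = 1.04e-73), and of the 245 Up peaks 1 did. Chromosome 19 held 53 of the Down peaks (13% against 1.30%, odds ratio 11.3), and 33 (8.07% against 1.35%, odds ratio 6.42) were annotated at a transcription termination site. Exons (5.13% against 1.11%, odds ratio 4.83), promoters (3.42% against 1.05%, odds ratio 3.33) and introns (53.1% against 43.1%, odds ratio 1.49) were also more frequent among the Down peaks. Intergenic peaks were fewer among the Down peaks (30.3% against 52.7%, odds ratio 0.39). A Down peak of the authors lay over most of ZNF274 itself (chromosome 19, 58183765 to 58220390). Median widths were 3876 bp for Down and 1061 bp for Up peaks. Neighbouring peaks are not independent, and these calls rest on the authors' test.

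**Figure D3:**
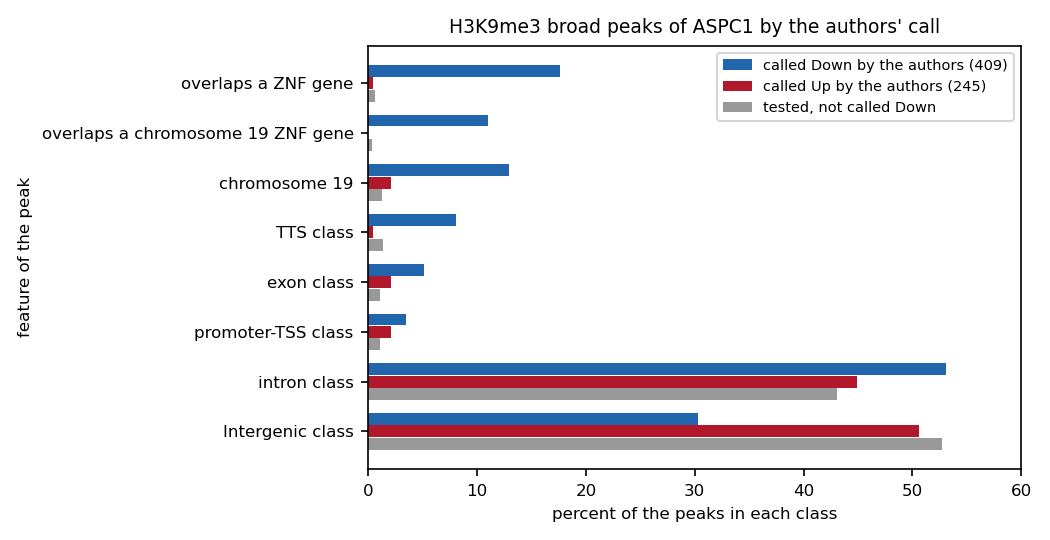
Percent of the authors' Down, Up and other tested H3K9me3 peaks that carry each feature. Zinc finger genes were overlapped by 17.6% of the Down peaks and by 0.408% of the Up peaks.

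In the libraries labelled siZNF274, zinc finger genes of chromosome 19 were higher in both lines. In ASPC1, 87 of 168 rose and 6 fell, with a median log2 fold change of 0.31 (camera, adjusted p = 1.16e-06, and adjusted p = 0.120 with an estimated correlation), and 138 of the 168 lay above 0. In CFPAC1, 60 of 223 rose and 5 fell, with a median of 0.17 (camera, adjusted p = 5.95e-06, and adjusted p = 0.120 with an estimated correlation), and 165 of the 223 lay above 0. ZNF529 (ENSG00000186020.13, chromosome 19, 36534774 to 36605276, 98.1% of its body under peaks) rose 3.13-fold in ASPC1, from 3.34 ± 0.36 to 10.4 ± 0.36 CPM, ZNF550 2.07-fold and ZNF432 2.00-fold. In CFPAC1, ZNF850 (ENSG00000267041.6, chromosome 19, 36714383 to 36772825) rose 1.90-fold, from 12.8 ± 1.13 to 24.3 ± 1.12 CPM, and ZNF506 1.59-fold. These zinc finger genes were chosen after their values were seen. All zinc finger genes together had 144 of 389 higher and 37 lower in ASPC1 (camera, adjusted p = 0.00235, and adjusted p = 0.285 with an estimated correlation) and 87 of 463 higher and 29 lower in CFPAC1 (camera, adjusted p = 0.00541, and adjusted p = 0.285 with an estimated correlation). Not every member went up: ZNF664, on chromosome 12, fell from 185 ± 6.22 to 69.9 ± 2.92 CPM in ASPC1 and from 151 ± 9.38 to 87.3 ± 7.19 CPM in CFPAC1.

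Cover by H3K9me3 was measured in ASPC1 only, and the genes covered there were also tested in CFPAC1 and Panc3.27. These H3K9me3-covered genes had 119 of 343 higher and 34 lower in ASPC1 with siZNF274 (median 0.24, camera, adjusted p = 0.00257, and adjusted p = 0.324 with an estimated correlation). In CFPAC1 they had 103 of 533 higher and 20 lower (median 0.14, camera, adjusted p = 9.77e-04, and adjusted p = 0.285 with an estimated correlation). Without zinc finger genes the covered genes no longer passed in either line (camera, adjusted p = 0.619 and 0.174), with medians of 0.15 over 176 genes in ASPC1 and 0.11 over 303 genes in CFPAC1. In sets added later, covered zinc finger genes had medians of 0.33 in ASPC1 and 0.18 in CFPAC1 (camera, adjusted p = 2.80e-06 and 1.17e-06). Neither call held (adjusted p = 0.626 and 0.396 with an estimated correlation). Zinc finger genes without any peak had medians of 0.079 and -0.019 (camera, adjusted p = 0.492 and 0.902). The difference between covered and uncovered zinc finger genes was not tested. With a limit of 25% of the gene body, covered genes did not pass in ASPC1 (camera, adjusted p = 0.0948) and passed in CFPAC1 (camera, adjusted p = 0.0228). With azacitidine none of the 3 planned sets passed in either line. The zinc finger genes of chromosome 19 then had 12 of 168 higher and 19 lower in ASPC1 (camera, adjusted p = 0.961) and 16 of 223 higher and 8 lower in CFPAC1 (camera, adjusted p = 0.573). In Panc3.27 with overexpression, zinc finger genes of chromosome 19 had 65 of 203 higher and 13 lower (median 0.11, camera, adjusted p = 0.00888, and adjusted p = 0.285 with an estimated correlation). Covered genes had 108 of 457 higher and 23 lower there (median 0.105, camera, adjusted p = 0.0176, and adjusted p = 0.324 with an estimated correlation), a call that ended without vector replicate 3 (camera, adjusted p = 0.0510) or without zinc finger genes (0.0681), where the median of the 251 genes left was also 0.105, or at 25% of the gene body (0.0948). All zinc finger genes did not pass in Panc3.27, with 99 higher and 55 lower of 436 (camera, adjusted p = 0.573).

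**Figure D4:**
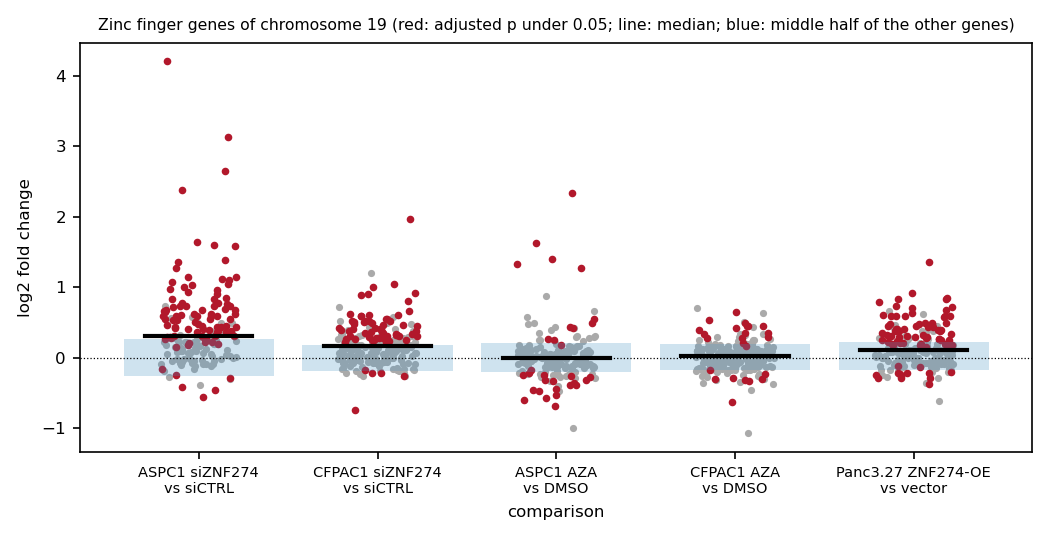
Log2 fold changes of the tested zinc finger genes of chromosome 19 in the 5 comparisons, with the median of each. The medians were 0.31 and 0.17 with siZNF274 in ASPC1 and CFPAC1, and 0.11 with overexpression in Panc3.27.

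The remaining 10 lists passed the test in none of the 5 comparisons. The H3K9me3 machinery had its lowest adjusted p (camera) of 0.156 in Panc3.27, with 3 of 26 higher and 12 lower, or 3 and 13 adjusted over the list alone. Clustered protocadherins came closest in CFPAC1 with azacitidine, with 2 of 45 higher and 8 lower, also adjusted over the list alone (median -0.33, camera, adjusted p = 0.0611). The leukocyte list reached camera, adjusted p = 0.0611 in CFPAC1 with azacitidine, with 3 of 7 higher and none lower, also adjusted over the list alone. Among them CD14 went from 1.79 ± 0.17 to 4.73 ± 0.27 CPM. The DNA methylation machinery had 3 of 20 higher and 6 lower in Panc3.27, or 3 and 7 adjusted over the list alone (camera, adjusted p = 0.0656). In ASPC1 with azacitidine its members UHRF1 and DNMT1, the maintenance methyltransferase, went from 51.8 ± 2.50 to 84.3 ± 4.55 CPM and from 172 ± 4.54 to 207 ± 12.4 CPM. Transcription kinases had none of 22 higher and 6 lower in CFPAC1 with azacitidine, or 1 and 7 adjusted over the list alone (camera, adjusted p = 0.125), and in CFPAC1 with siZNF274 their member CDK7 went from 22.5 ± 1.01 to 17.9 ± 1.93 CPM. In ASPC1 with siZNF274 CDK7 went from 47.2 ± 2.79 to 39.4 ± 1.08 CPM, while 3 of 22 transcription kinases rose and 3 fell, also adjusted over the list alone. Neuroendocrine and neural genes had their lowest adjusted p (camera) of 0.186 in CFPAC1 with azacitidine (5 of 17 higher, 1 lower, also adjusted over the list alone), mitochondrial mRNA of 0.139 in CFPAC1 with siZNF274 (0 of 13 called, also adjusted over the list alone), acinar genes of 0.125 in CFPAC1 with siZNF274 (1 of 4 higher, also adjusted over the list alone) and fibroblast genes of 0.150 in Panc3.27 (1 of 8 higher, 3 lower, also adjusted over the list alone). The Prader-Willi locus could be tested in CFPAC1 only, where none of 5 genes was called, also adjusted over the list alone (camera, adjusted p = 0.823 with siZNF274 and 0.860 with azacitidine). Median and mean differed in sign for none of the called lists except the squamous list of ASPC1 with azacitidine, and the median, mean and test differed in sign for 5, 4, 9, 2 and 2 lists without a call in the 5 comparisons in the order given here.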

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

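The tests of swapped labels, of nuclear RNA, of a loss of H3K9me3, of the zinc finger difference between lines and of a response to any siRNA, and the comparison of both control groups, were chosen after the result was seen. The genes and lists of the next 3 paragraphs stand here because the change differed between ASPC1 and CFPAC1 in a test of the difference itself. Differences are log2, ASPC1 minus CFPAC1.

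The siZNF274 change differed between the lines for 3178 genes and the azacitidine change for 3306 (edgeR). Of 40 drawn splits of the libraries within each line, 4 gave as many genes for siZNF274 as the real split, itself included, with a highest other of 4642. For azacitidine 2 did, with a highest other of 6486. The other siZNF274 splits as large kept the ASPC1 libraries of each group together and mixed those of CFPAC1. The azacitidine split with 6486 genes exchanged the groups of 1 line, so that it sums the changes of both lines. This points to a structure of the samples: splits that keep the groups of 1 line still carry its change, and those that mixed both lines gave 0 genes. Whether chance can be excluded is therefore not settled by these splits.

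With siZNF274, the classical list differed by -0.74 (camera, adjusted p = 0.00171), basal-like by 0.26 (adjusted p = 0.0348), epithelial by -0.30 (3.69e-06), foregut by -0.12 (0.0348), cell cycle by -0.074 (0.0209), integrated stress response by -0.45 (1.60e-10), NF-kB by 0.31 (0.00803), cholesterol synthesis by 0.50 (1.55e-16) and histones by -0.34 (1.08e-07). None of these held with an estimated correlation, where the lowest adjusted p was 0.193. With azacitidine, the classical list differed by -1.34 (6.25e-11), basal-like by 0.47 (0.00218), epithelial by -0.47 (8.59e-09), mesenchymal by 0.52 (6.53e-10), foregut by -0.21 (0.00218), interferon by -0.25 (0.00636), antigen presentation by -0.21 (0.0309) and cholesterol synthesis by -0.52 (4.75e-14). Of these the classical, basal-like and mesenchymal differences held with an estimated correlation (adjusted p = 0.00367, 0.0377 and 0.00460).

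Of the 32 genes named by size for siZNF274, 20 differed (edgeR, highest adjusted p = 0.0366). Above 0 were BMF 1.61, CDKN1C 2.14, FNDC4 1.87, COL7A1 2.17, CDSN 3.57, CSF1 2.00, LIMD2 1.64, ADAMTS7 1.69 and ZBED2 0.82. Below 0 were KRT23 -3.00, SLC44A4 -2.70, SLC5A1 -2.57, PLEKHB1 -2.15, CEACAM5 -1.14, SLC28A3 -2.20, GDF15 -2.20, GJB1 -2.54, ANXA13 -2.79, ENG -1.41 and ATP6V0E1 -0.44. Of the 32 for azacitidine, 21 differed (edgeR, highest adjusted p = 0.00788). Above 0 were NPTX1 3.82, MMP1 2.71, TOX2 3.78, DUSP5 4.21, BMP6 4.64, SLC37A2 2.45, FERMT3 1.84, KRT13 1.92, IL11 2.06 and CPED1 3.72. Below 0 were SLC5A1 -3.46, PRR15L -3.09, COL28A1 -2.49, GJB1 -2.43, SLC44A4 -2.04, ARHGEF38 -2.27, INPP5D -3.11, GCNA -1.71, S100P -1.23, KLHDC7B -2.40 and MUC5B -3.05.

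ZNF274 was not lower in the libraries labelled siZNF274. Exchanged siRNA labels would make its fold that of a knockdown turned over, and the highest upper 95% bound over both lines was 1.31, which argues against a swap after any stronger knockdown. The count table lists no gene that overlaps ZNF274 (0% of its CPM), so reads of overlapping transcripts outside the table stay open. An siRNA with little effect on the mRNA when the RNA was taken stays open and was not tested.

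Zinc finger genes of chromosome 19 were higher with siZNF274 in both lines, and neither call held with an estimated correlation (camera, adjusted p = 0.120 in each). The rise was larger in ASPC1, with a median difference of 0.20 (camera, adjusted p = 3.86e-05, and adjusted p = 0.0225 with an estimated correlation). Among 10000 lists matched for expression the highest median was 0.0886 in CFPAC1 against 0.17 observed, and 0.205 in ASPC1 against 0.31, which argues against low expression alone. A larger nuclear share stays open: with azacitidine in ASPC1 the MALAT1 share was 1.65-fold and these genes lay 0.000694 above the others, with azacitidine in CFPAC1 these values were 1.31-fold and 0.026, and in Panc3.27 1.39-fold and 0.098, against 1.44-fold and 0.32 with siZNF274 in ASPC1 and 1.13-fold and 0.18 in CFPAC1. A loss of H3K9me3 stays open too: covered zinc finger genes in the authors' Down peaks had a median of 0.19 (32 genes) and the others 0.38 (135 genes), a difference of -0.18 (permutation test, p = 0.0864), and the peaks come from a hairpin, not from the siRNA.

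The siCTRL libraries differed from DMSO in stress genes in ASPC1 and in interferon genes in CFPAC1. No single library made this, since the highest adjusted p without 1 library was 5.25e-85 (camera). A response to any siRNA alike in both lines would raise both lists in both lines. The interferon list of ASPC1 had a median of -0.21 (camera, adjusted p = 0.0141, and adjusted p = 0.605 with an estimated correlation). The stress list of CFPAC1 had 7 of 29 genes higher and 1 lower, with a median of 0.043 (camera, adjusted p = 0.0771). This argues against such a response for both lists only. They were chosen because each stood out in 1 line, so they do not speak for other genes. Transfection that acts differently in each line, and any other difference between the siRNA and the drug experiments, cannot be told apart because the design confounds them.

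With 6 libraries the splits are too few for a share under 0.05, so a low share cannot exclude chance. The real gene counts were 7400, 4483, 5796, 4652 and 6404 for siZNF274 in ASPC1 and CFPAC1, azacitidine in ASPC1 and CFPAC1, and overexpression, and the highest other split gave 0 genes in each. The real list counts were 10, 8, 9, 5 and 9, and the highest others 9, 9, 8, 9 and 8. Splits with as many were 1, 4, 1, 9 and 1 of 10 for lists and 1 of 10 for genes in each. For siZNF274 and azacitidine in CFPAC1, splits that mixed the groups thus gave as many lists as the real split. These list counts therefore do not stand above chance. The other splits called up to 9 lists with 0 genes called, so a count of lists alone does not show a difference between groups. For shared calls, 1 of 100 drawn splits, the real one, gave as many in each of 6 pairs of comparisons. Since every other split of a comparison called 0 genes, this outcome was fixed and does not show that calls are shared beyond chance. The real counts were 2490 (siZNF274 in both lines), 1641 (azacitidine in both lines), 2524 and 1003 (siZNF274 and azacitidine in ASPC1 and in CFPAC1), and 1791 and 1466 (siZNF274 in each line and overexpression). The highest others were 0, 521, 849, 0, 1258 and 0, and those above 0 are the real groups with the direction of 1 comparison turned.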

How the results depend on the processing

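The tests of peak and zinc finger sets that leave out 1 library, rescale or use peaks called in both groups, and the shared calls without 1 library, were chosen after the result was seen. Of the values that answer a comparison, 291 stayed the same under the alternatives. For a count this means within 1.5 times, and for a test the same direction and side of the threshold. Of the others, 12 lost a call, 1 gained it and 17 counts moved by more than 1.5 times. For single genes and further sets, 7885 kept their direction and side of the threshold, 256 lost a call and 7 changed direction. Over the settings that kept every compared library, genes called ran from 6580 to 7928 for siZNF274 in ASPC1 and 3299 to 4728 in CFPAC1. They ran from 5539 to 6442 for azacitidine in ASPC1, 4564 to 5472 in CFPAC1, and 5671 to 6817 for overexpression. With the replicate number as a replicate block they were 7928, 4728, 6442, 4875 and 6505. Without 1 library they ran from 6302 to 7330 for siZNF274 in ASPC1 and 3227 to 4755 in CFPAC1. For azacitidine in ASPC1 and CFPAC1 these ranges were 4629 to 5745 and 3236 to 4882, and for overexpression 5147 to 6218.

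In the same order, an estimated correlation left 1, 4, 4, 2 and 4 lists, and fry, which tests a list without its background, called 17, 15, 15, 13 and 18. For azacitidine in CFPAC1, between 4 and 10 lists were called without 1 library, with 10 without DMSO replicate 1, and the cause was not tested.

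ZNF274 in ASPC1 with siZNF274 lay between 0.028 and 0.28 without 1 library, and was called higher without siCTRL replicate 3 (0.28; edgeR, adjusted p = 0.0445). ZNF274 in CFPAC1 with azacitidine was 0.16 without a filter (edgeR, adjusted p = 0.161), 0.16 with the replicate block (adjusted p = 0.0578) and 0.16 with DESeq2 (adjusted p = 0.0516). Without 1 library it lay between 0.14 and 0.18, and the call ended without AZA replicate 1, 2 or 3 (adjusted p = 0.115, 0.0689 and 0.148) and without DMSO replicate 1 or 2 (0.108 and 0.106). Over all its alternatives the adjusted p ran from 0.0157 to 0.161. The cause was not tested.

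For siZNF274 in ASPC1, covered genes had adjusted p (camera) of 0.324 with an estimated correlation, 0.0948 at 25% cover and 0.619 without zinc finger genes, within a range of 8.49e-05 to 0.619. Zinc finger genes had 0.285 with an estimated correlation, within 8.00e-04 to 0.285. Leaving out zinc finger genes removes members with a median of 0.33 and keeps those with 0.15, and for the others the cause was not tested. With an absolute log2 fold change of at least 1, which fewer genes pass, shared calls were 55 and 66 between lines for siZNF274 and azacitidine, 236 and 34 between both treatments in ASPC1 and CFPAC1, and 34 and 13 between siZNF274 in ASPC1 and CFPAC1 and overexpression. Opposite calls were then 4, 11, 25, 14, 40 and 9 in that order, where 4.31, 4.52, 25.8, 3.46, 7.93 and 2.08 were expected. The 11 of azacitidine in both lines lay above expectation, while without this limit 521 lay below the 731 expected. The 14 of both treatments in CFPAC1 also lay above expectation, while without this limit 582 lay near the 574 expected. For siZNF274 in ASPC1 and overexpression, opposite calls thus outnumbered shared ones (40 with 7.93 expected, 34 with 9.53 expected), while without this limit shared ones were more (1791 against 1258). For CFPAC1 the 9 opposite calls also lay above the 2.08 expected, while without this limit 588 lay below the 788 expected.

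The 7 reversals were in azacitidine sets without a call (camera). Zinc finger genes of chromosome 19 in ASPC1 had adjusted p = 0.990 without AZA replicate 2 and without DMSO replicate 1, and covered genes there 0.990 without DMSO replicate 1. In CFPAC1, zinc finger genes had 0.925 without AZA replicate 1 and 0.712 without DMSO replicate 3, and covered genes 0.897 without AZA replicate 2 and 0.656 without DMSO replicate 2. Over each library left out, the ranges were 0.937 to 0.990 and 0.635 to 0.990 for both sets in ASPC1, and 0.661 to 0.983 and 0.656 to 0.927 in CFPAC1. The cause was not tested. A stricter limit on the peak score was not run, because the score has 1 value in all peaks. At these depths, simulated 2-fold changes were recovered for 80.8% to 87.9% of genes within a line.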

Other observations

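The comparison of control groups was among the tests chosen after the result was seen. In ASPC1, the siCTRL libraries had higher integrated stress response genes than the DMSO libraries: 25 of 27 were higher and 1 lower, with a median fold of 2.66 (camera, adjusted p = 1.89e-92, and adjusted p = 0.00652 with an estimated correlation). CHAC1, a glutathione-degrading enzyme induced by ATF4, was at 36.9 ± 9.86 CPM with siCTRL and 2.40 ± 0.20 CPM with DMSO (n = 3 each). PSAT1 was at 168 ± 13 and 24.2 ± 1.06 CPM, and the mTORC1 inhibitor DDIT4 at 432 ± 95.1 and 46.3 ± 5.83 CPM. With siZNF274, CHAC1, PSAT1 and DDIT4 were at 22.3 ± 3.24, 110 ± 11.8 and 315 ± 52.5 CPM. NF-kB and inflammatory genes were also higher with siCTRL than with DMSO, with a median of 0.51 (camera, adjusted p = 7.79e-06). Classical PDAC, interferon response and cell cycle genes were lower, with medians of -0.29, -0.21 and -0.12 (camera, adjusted p = 0.0170, 0.0141 and 0.0196). None of these further calls held with an estimated correlation, where the lowest adjusted p (camera) was 0.137.

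In CFPAC1 the siCTRL libraries instead had higher interferon response genes: 42 of 48 were higher and none lower, with a median fold of 2.06 (camera, adjusted p = 7.15e-123, and adjusted p = 0.00168 with an estimated correlation). The antiviral genes IFI44L, OAS2 and MX1 were at 88.7 ± 7.17, 122 ± 15.4 and 276 ± 38.3 CPM with siCTRL and at 16.1 ± 0.63, 26.7 ± 0.90 and 63.1 ± 5.98 CPM with DMSO. With siZNF274 these 3 genes were at 98.4 ± 14, 104 ± 21.6 and 153 ± 31.1 CPM, and the list did not pass the test against siCTRL, with a median of -0.01 (camera, adjusted p = 0.609). Antigen presentation genes had 17 of 24 higher and none lower, with a median of 0.44 (camera, adjusted p = 2.74e-21), and cholesterol synthesis 17 of 25 and none, with a median of 0.27 (camera, adjusted p = 3.87e-16, and adjusted p = 0.0417 with an estimated correlation). Mesenchymal genes had 3 of 28 higher and 10 lower, with a median of -0.21 (camera, adjusted p = 8.91e-06, and adjusted p = 0.0364 with an estimated correlation), while with siZNF274 this list was raised against siCTRL by a median of 0.21.

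Over all genes, 2569 were higher and 2305 lower in siCTRL than in DMSO in ASPC1 (edgeR, of 16186), and 1322 and 1488 in CFPAC1 (of 18103).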
